A study of Mus musculus with 18 samples.

How the data were processed

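Bulk RNA sequencing was carried out on skin of C57BL/6 mice aged 8-12 weeks. The 18 libraries fall into 3 groups of 6, labelled PBS, detergent A and detergent B, where PBS is the phosphate-buffered saline control. Per the labels' protocols, skin sections were kept in RNAlater, homogenised in Qiazol with a gentleMACS device, and total RNA was isolated with an RNeasy Plus Universal kit before standard Illumina library preparation. The labels do not give the dose, the duration of treatment, the body site, the cage or the day of collection. They also do not say whether each library comes from its own animal, so the p-values measure the spread between these samples.

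The deposited files hold whole-number counts of reads per gene, which the authors did not normalise, judging from totals that differ between libraries. Per the submitters' processing notes, STAR, featureCounts and the GRCm38.p5 build were used. Tool versions, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Genes of near-identical families, such as the Stfa, Sprr2, Serpinb3, Lce1 and Krtap1 families, are therefore uncertain as single genes, as are overlapping and antisense genes. Each file lists 41605 Ensembl gene IDs, of which 41519 were matched to the GENCODE M21 annotation of GRCm38 for symbols and coordinates, and 86 were not. Totals ranged from 17312623 to 29599018 counts per library.

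Genes were tested with edgeR 4.0.16 in R 4.3.3. The default filter on low counts kept 16836 genes, which held at least 99.89% of the counts of each library. Library sizes were scaled with TMM, and a quasi-likelihood model with group as its only term was fitted to all 18 libraries, which left 15 residual degrees of freedom. Each detergent was compared with PBS, the comparison the series describes, and detergent B was compared with detergent A. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic.

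A total of 45 gene lists covering barrier, inflammatory, stress, cell type and tissue markers, all with at least 3 genes measured, were scored in each library as the mean log2 CPM of their members with a prior count of 2. Differences of group means were tested with an exact two-sided permutation test over the 924 assignments of 12 libraries to 6 against 6, and adjusted over the 45 lists. The smallest p this test can give is 0.002165. The limma package (3.58.1) supplied the camera set tests, run with a preset and with an estimated correlation between genes. Camera asks whether the genes of a list change more than the other genes, not whether the list score differs between groups. Adjusted p-values given below with an estimated correlation are from camera.

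Genes named in the text follow a fixed rule. For each detergent against PBS these were the 8 largest increases and the 8 largest decreases among genes past the threshold. These genes also needed a mean of at least 1 CPM in the higher group and at least 5 of 6 treated libraries on the called side of the PBS mean. Here and below, counts of libraries above or below a group mean use the mean of log2 CPM. Genes without a symbol, predicted genes, Rik clones and pseudogenes were passed over. The rule took 5 in each direction for detergent B against detergent A, or the 5 smallest p-values if none passed. It added up to 3 members of each list past its threshold, and 12 fixed genes whatever their result, which were Flg, Ivl, Cldn1, Ocln, Tslp, Il33, Ccl11, Krt6a, Krt16, S100a8, S100a9 and Il1b. The lists, this rule, the tests and the settings below, unless stated otherwise, were chosen before the data were examined.

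Other settings tried were DESeq2 1.42.0, limma voomWithQualityWeights, other size factors and filters, a fit on only the 12 libraries compared, a replicate block, a non-robust fit, a test against a fold of 1.5, tissue scores as covariates, tissue genes left out, and each library left out in turn. Corrections for GC content and gene length in 20 bins, and further fits with the hair keratins score as a covariate, were added after seeing the data. On simulated counts for detergent A against PBS, edgeR recovered 75% of genes changed 2-fold and 38% of genes changed 1.5-fold with 1 false call among 114 genes called, and DESeq2 recovered 83% and 50% with 19 false calls. The simulation drew genes independently, so it does not carry structure that libraries share.

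No library was left out. Between the counts of any pair of libraries, the chi-square statistic per gene was at least 9.481, so no pair agreed within sampling noise. All 18 libraries had Xist at 484.7 CPM or more and Ddx3y at 0.135 CPM or less, the levels of female tissue.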

Results

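Gene expression was measured by RNA sequencing in mouse skin treated with PBS, detergent A or detergent B, with 6 libraries per group. Mean total counts were 21863011 ± 4375256 (SD, n = 6) for PBS, 21797656 ± 2686736 (SD, n = 6) for detergent A and 22037488 ± 4282859 (SD, n = 6) for detergent B. Hair keratin genes varied widely between libraries. The first principal component held 42.6% of the variance and followed the hair keratins score across the 18 libraries, with a Pearson r of -0.98 and a Spearman rho of -0.96 (p = 1e-05 for both by permutation, the smallest that 100000 resamples can give). Without the 2 libraries farthest from the median score r was -0.98, and with values centred on the group means it was -0.97. The hair keratins score ranged from -5.84 to 1.85 relative to the PBS mean on the log2 scale, with PBS replicate 6 at -2.98 against -0.34 to 1.85 in the other PBS libraries.

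The series asks how skin treated with each detergent compares with PBS. With detergent B, 13 of 30 cornified envelope genes, 13 of 26 barrier lipid genes and 5 of 12 epithelial alarmin genes rose, while the epithelial cytokine genes Il33 and Tslp did not pass. The 3 list scores passed the exact permutation test, but not with the hair keratins score as a covariate in limma (adjusted p = 0.0906, 0.0906 and 0.3569). That fit changed the test as well as adding the covariate, so the lost calls cannot be laid to the covariate alone. Camera with an estimated correlation, which sets list genes against the other genes, called none of the 3 lists (adjusted p = 0.2628 for each). Ivl, which encodes the envelope precursor involucrin, rose 2.1-fold from 229 ± 42.7 to 483 ± 77.1 CPM (SD, n = 6 per group). Casp14, a protease of terminal differentiation, rose 2.4-fold from 449 ± 53.8 to 1077 ± 224 CPM. Flg, which encodes filaggrin, rose 2.42-fold from 767 ± 236 to 1853 ± 395 CPM. Il1f6, also called Il36a, rose 3.06-fold from 19.9 ± 5.16 to 60.8 ± 14.3 CPM. Among 16836 genes, 332 were higher and 182 were lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test, and 112 of these 514 differed at least 2-fold.

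Stfa3, a cystatin family gene on chromosome 16 from 36450537 to 36455392 (GRCm38), shared the smallest adjusted p, 0.006215 by edgeR, with Il1f6 and the predicted gene Gm17767, and had a log2 fold change of 2.35 ± 0.33 (SE) and higher values in 6 of 6 libraries than the PBS mean. The largest increases by the naming rule were Spink7, a protease inhibitor, at 9.9-fold, Pla2g4d, a phospholipase, at 8.07-fold, Serpinb3a at 6.87-fold, Saa3, an acute phase gene, at 6.34-fold, Tcf23 at 6.16-fold, Sprr2d at 6.06-fold, and the Stfa-region genes BC117090 and BC100530 at 5.75-fold and 5.52-fold. BC100530 was the most abundant of these, at 814 ± 248 CPM against 148 ± 87.5 CPM. The largest decreases were in genes of low level. The hair shaft genes Krtap1-4 and Krtap1-3 had log2 fold changes of -3.94 ± 1 and -3.87 ± 0.98 (SE), and both had PBS means that rested largely on PBS replicate 1, at 5.22 and 9.38 CPM. Cryaa, a crystallin gene, fell by 2.22 ± 0.37 on the log2 scale, from 2.32 to 0.489 CPM. Kank4, Prr7, Gpr37 and Stra6, a retinol transporter gene, had log2 fold changes between -1.38 and -1.52. Fgf5, a regulator of the end of hair growth, had one of -1.47 ± 0.37 (SE).

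Of the 45 lists, 11 passed the exact permutation test for detergent B against PBS, 10 of them upward. Some of these lists share genes, so the 11 calls are not separate results. Klk5 is in the cornified envelope and protease lists, Il1f6 in the stress keratins and epithelial alarmin lists, and Il18 in the alarmin and inflammasome lists. In the cornified envelope list the score rose by 0.74 on the log2 scale (adjusted p = 0.02435, exact permutation test, and adjusted p = 0.2628 with an estimated correlation) and 13 of 30 measured genes rose, with 24 rising and 1 falling, Krt77, when adjusted over the list alone; Casp14, Ivl and Calml3 led it. The late cornified envelope score rose by 1.12 (adjusted p = 0.01948, exact permutation test, and adjusted p = 0.2628 with an estimated correlation), and Lce3e (4.85-fold), Lce3c (3.31-fold), Lce1g (2.09-fold) and Lce1f were the 4 of 20 genes that rose, against 17 adjusted over the list alone; Lce1f falls outside the naming rule. The small proline-rich score rose by 1.8 (adjusted p = 0.01948, exact permutation test, and adjusted p = 0.2628 with an estimated correlation), with Sprr2d, Sprr2e (5.5-fold) and Sprr2h (3.62-fold) as the 3 of 12 that rose, against 11 adjusted over the list alone. Barrier lipid synthesis rose by 0.53 (adjusted p = 0.01948, exact permutation test, and adjusted p = 0.2628 with an estimated correlation), and 13 of 26 genes rose, with 22 rising and 1 falling, Fads2, adjusted over the list alone. Krt77 and Fads2 fall outside the naming rule and were named after their values were seen. Its examples were the ceramide enzyme gene Degs2, from 25.1 ± 8.89 to 93.7 ± 16.6 CPM (SD), Ugcg at 1.53-fold and Sptlc1 at 1.48-fold.

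Proteases and inhibitors of the cornified layer rose by 0.58 (adjusted p = 0.01948, exact permutation test, and adjusted p = 0.2628 with an estimated correlation), with 6 of 19 genes rising, among them Klk8 (1.8-fold), Klk5 (1.77-fold) and Ctsd (1.43-fold), and 15 rising and 1 falling, St14, which is outside the naming rule, adjusted over the list alone. The stress keratins list rose by 1.04 (adjusted p = 0.03896, exact permutation test, and adjusted p = 0.3933 with an estimated correlation), and 7 of 19 genes rose, 8 adjusted over the list alone. The members that led it were not keratins but Stfa3, Il1f6 and Serpinb12 (3.49-fold). Krt16 was at 2072 ± 973 CPM against 774 ± 525 CPM and Krt6a at 1487 ± 897 against 850 ± 565 CPM (SD), and neither passed (adjusted p = 0.1699 and 0.4413, edgeR). Antimicrobial peptides rose by 0.77 (adjusted p = 0.02435, exact permutation test, and adjusted p = 0.2628 with an estimated correlation), with Wfdc12 (5.25-fold) and Defb1 (1.88-fold) as the 2 of 13 that rose, against 5 adjusted over the list alone. Lcn2 had a fold of 2.53 and did not pass (adjusted p = 0.05959, edgeR).

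Epithelial alarmins rose by 0.48 (adjusted p = 0.02435, exact permutation test, and adjusted p = 0.2628 with an estimated correlation). In that list Il1f6, Il1f8 (2.51-fold), Il1a (1.61-fold), Il18 (1.98-fold) and Il1f9 were the 5 of 12 genes that rose over all genes tested, and 5 rose and 1 fell, Crlf2, adjusted over the list alone; Il1f9 and Crlf2 fall outside the naming rule. Inflammasome genes rose by 0.43 (adjusted p = 0.03896, exact permutation test, and adjusted p = 0.2628 with an estimated correlation), with the gasdermin genes Gsdma (1.61-fold) and Gsdmc (2.79-fold) and the cytokine gene Il18 as the 3 of 16 that rose, against 7 adjusted over the list alone. Mitochondrial respiration rose by 0.21 (adjusted p = 0.04427, exact permutation test, and adjusted p = 0.4187 with an estimated correlation), with Ndufa4 (1.52-fold) the 1 of 25 genes past the threshold and 15 adjusted over the list alone. The mitochondrial call was lost in 10 of 12 fits that left out 1 of the libraries compared, the inflammasome call in 9 and the stress keratins call in 8, and the mitochondrial score difference was 0.14 without detergent B replicate 4. Ndufa1 and Atp5o had folds of 1.32 and 1.27 and did not pass (adjusted p = 0.07093 and 0.05898, edgeR).

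Tight junction was the list that fell with detergent B, by 0.18 on the log2 scale (adjusted p = 0.01948, exact permutation test, and adjusted p = 0.4376 with an estimated correlation). Its 1 gene past the threshold of 22 was Cldn3, from 6.12 ± 1.31 to 3.21 ± 0.456 CPM (SD), with Cldn3 and Magi1 as the 2 that fell adjusted over the list alone. Magi1 and Cldn7 had log2 fold changes of -0.59 and -1.64 and did not pass over all genes tested, and Cldn7 was at 0.583 CPM with PBS. The claudin and occludin genes with high levels in these samples, Cldn1 (349 ± 22.1 against 355 ± 20 CPM) and Ocln (33.7 ± 3.94 against 32.4 ± 3.53 CPM), gave adjusted p-values of 0.8394 and 0.7303 by edgeR.

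Other fixed genes did not pass with detergent B. S100a8 was at 42.7 ± 57.1 CPM against 9.05 ± 3.46 CPM with PBS, and S100a9 at 46.8 ± 52 against 14.5 ± 6.8 CPM (SD, n = 6), with adjusted p-values of 0.1234 and 0.1752 by edgeR. Il33, Tslp, Ccl11 and Il1b had folds of 1.66, 1.2, 1.23 and 1.51, with adjusted p-values from 0.3436 to 0.7111 (edgeR). The Il1b mean of 12 ± 10.6 against 7.92 ± 2.45 CPM (SD) rested largely on detergent B replicate 4, at 32.5 CPM. Only 3 of 6 libraries were above the PBS mean. The hair keratins score differed from PBS by -2.94 (adjusted p = 0.06494, exact permutation test), opposite in sign to the cornified envelope and barrier lipid scores. The melanocyte score differed by -0.96 (adjusted p = 0.2706, exact permutation test). Without PBS replicate 6 these differences were -3.54 and -1.49 and both passed (adjusted p = 0.03479 for each, exact permutation test). That library had the lowest PBS value of both scores, so leaving it out widens both differences. With any other of the compared libraries left out, the melanocyte score did not pass, and the hair keratins score passed only without detergent B replicate 3.

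With an estimated correlation in camera, 0 of the 45 lists passed for detergent B (lowest adjusted p = 0.2628), and with the hair keratins score as a covariate no gene passed by edgeR, although 1822 genes had an unadjusted p under 0.05 and DESeq2 with that covariate called 88 higher and 89 lower and voomWithQualityWeights 56 and 75. With that covariate all 514 genes kept their sign and 511 had an unadjusted p under 0.05, while their median absolute log2 fold change went from 0.59 to 0.42 and their median SE from 0.14 to 0.13. The total of 514 genes ranged from 28 without PBS replicate 3 to 1888 without PBS replicate 6, was 1391 by DESeq2 and 5074 by voomWithQualityWeights, and after a GC correction was 230 higher and 61 lower.

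**Figure D1:**
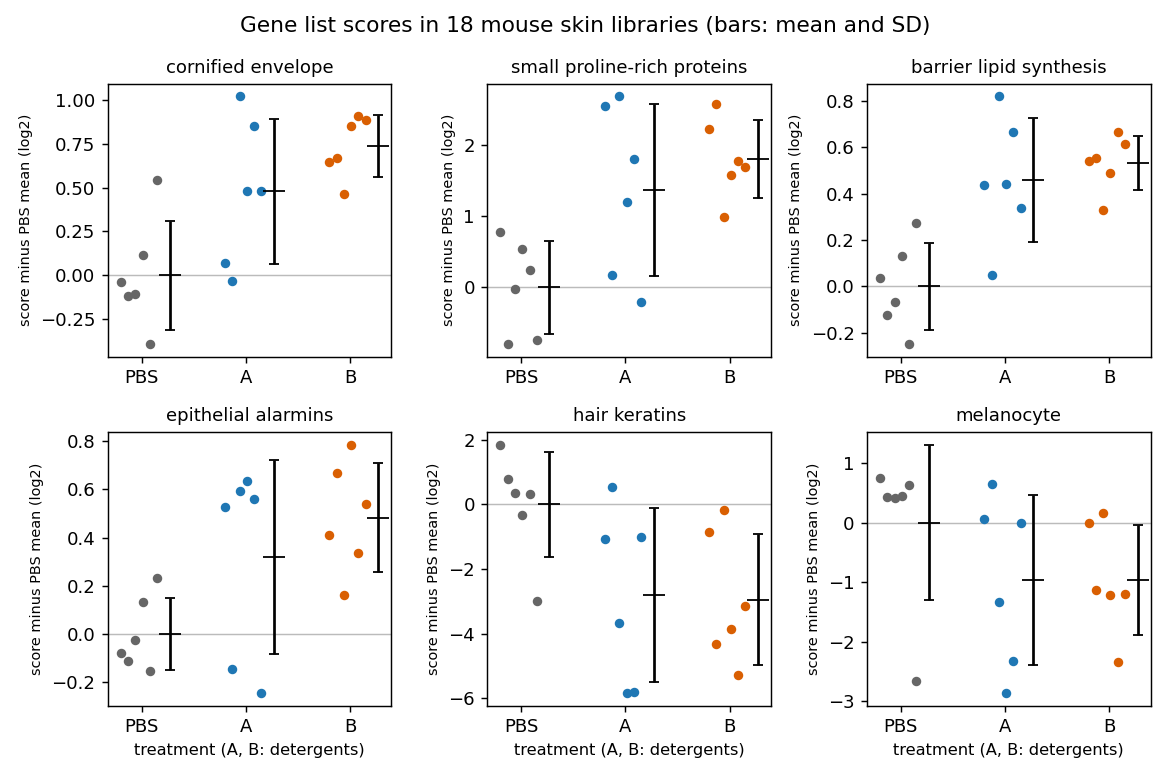
Scores of 6 gene lists, as mean log2 CPM minus the PBS mean, in each of the 18 libraries (points), with the group mean and SD (bars) for PBS, detergent A and detergent B. For small proline-rich proteins the 6 detergent B libraries sit between 0.988 and 2.566, all above the 6 PBS libraries, and PBS replicate 6 stands at -2.98 for hair keratins.

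With detergent A, few genes passed. Degs2 rose 2.91-fold, from 25.1 ± 8.89 to 73.3 ± 32.6 CPM (SD, n = 6 per group; edgeR adjusted p = 0.03919). Il1f8, also called Il36b, rose 2.12-fold and Glrx, a glutaredoxin gene, rose 2.03-fold. Twf1, Zfp772 and Cpeb2 rose 1.63-fold, 1.53-fold and 1.51-fold. In all, 9 genes were higher and 23 lower among 16836, and all 6 named increases were above the PBS mean in 6 of 6 libraries.

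The named decreases with detergent A were in genes of low to moderate level. Cryaa fell by 1.86 ± 0.36 (SE) on the log2 scale, Hic1 by 1.23 ± 0.23 and Eva1b by 1.1 ± 0.19. Cited4, Metrn, Crocc, Scarf2 and the homeobox gene Hoxb2 had log2 fold changes from -0.74 to -0.88. Barrier genes of the fixed set did not pass. Ivl was at 409 ± 126 against 229 ± 42.7 CPM (edgeR adjusted p = 0.0548) and Flg at 1273 ± 611 against 767 ± 236 CPM (edgeR adjusted p = 0.1801). Krt16 and Krt6a had folds of 3.16 and 2.76, S100a8 and S100a9 of 2.8 and 3.19, Il33 of 2.43 and Il1b of 2.3, with edgeR adjusted p-values from 0.1598 to 0.3348. Detergent A replicate 1 had the highest value of each of these genes, with S100a8 at 75.1, S100a9 at 130 and Il1b at 59.9 CPM. Il1b was at 18.3 ± 22.7 CPM (SD) and lay above the PBS mean in only 2 of 6 libraries. Cldn1, Ocln, Tslp and Ccl11 had folds of 1.09, 1.07, 0.956 and 0.933 and did not pass either.

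None of the 45 lists passed for detergent A. The lowest adjusted p, 0.1623 by exact permutation test, was shared by tight junction (-0.15), barrier lipid synthesis (0.46) and dendritic and Langerhans cell markers (-0.45). In the barrier lipid list, 1 of 26 genes rose over all genes tested, Degs2, and 23 rose and 1 fell, Fads2, adjusted over the list alone. Adjusted in that way, 18 of 30 cornified envelope genes, 10 of 12 small proline-rich genes, 14 of 19 proteases and inhibitors, 14 of 23 cholesterol synthesis genes and 5 of 20 late cornified envelope genes rose and none fell, against 0 over all genes tested by edgeR. Their scores differed from PBS by 0.48, 1.36, 0.44, 0.35 and 0.65 (adjusted p = 0.1732 for each, exact permutation test). For stress keratins 9 of 19 rose adjusted over the list alone, with a score difference of 0.83 (adjusted p = 0.1794, exact permutation test). The hair keratins score differed by -2.81 from PBS (adjusted p = 0.1732, exact permutation test). No gene remained past the threshold by edgeR with the hair keratins score as a covariate (1728 at an unadjusted p under 0.05) or with a GC correction (2677), and with the hair covariate DESeq2 called 10 higher and 100 lower and voomWithQualityWeights 3 and 43. All 32 genes kept their sign and an unadjusted p under 0.05 in both edgeR fits, and their median absolute log2 fold change went from 0.7 to 0.63 with the hair covariate and to 0.57 with the GC correction, with a median SE of 0.13 before and of 0.14 and 0.13 after. The total of 32 was 0 without any one of PBS replicates 1, 2 or 3, detergent A replicates 1, 3 or 5, or detergent B replicates 5 or 6. Where it was 0, the smallest adjusted p was 0.05158 to 0.133 (edgeR), against 0.03919 in the main fit. In these fits 2133 to 3124 genes had an unadjusted p under 0.05, against 3158 in the main fit. The total was 888 without PBS replicate 6, 797 by DESeq2 and 3914 by voomWithQualityWeights.

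**Figure D2:**
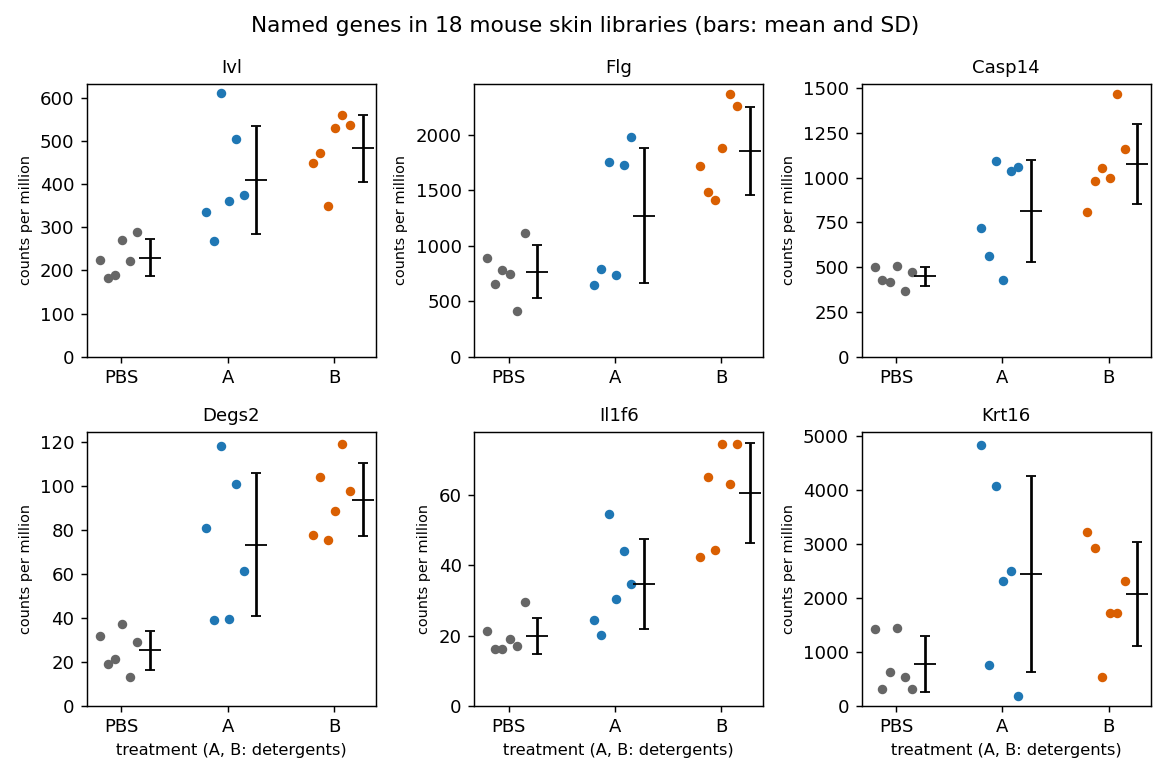
CPM, which are counts scaled by library size, of Ivl, Flg, Casp14, Degs2, Il1f6 and Krt16 in each of the 18 libraries (points), with the group mean and SD (bars), on linear axes from 0. The 6 detergent B libraries lie between 350 and 559 CPM for Ivl, all above the PBS libraries at 182 to 288 CPM.

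Detergent B was compared with detergent A to test whether they differ. No gene passed by edgeR, DESeq2 or voomWithQualityWeights, and 550, 770 and 578 had an unadjusted p under 0.05. Each count is a smaller share of the genes tested (16836, 28040 and 16836) than the 0.05 that unchanged genes would give. The smallest p-values belonged to Als2cr12 (1.65-fold), Rom1 (1.39-fold), Chil1 (1.85-fold), Il1f6 (60.8 ± 14.3 against 34.7 ± 12.8 CPM, SD) and Thbs4 (2.17-fold), each higher with detergent B in 6 of 6 libraries than the detergent A mean, with an edgeR adjusted p of 0.9887. Ivl and Flg had folds of 1.18 and 1.46, Krt6a and Krt16 of 0.634 and 0.848, S100a8 and S100a9 of 1.67 and 1.01, and Cldn1 and Ocln of 0.899 and 0.969. S100a8 was at 42.7 ± 57.1 against 25.5 ± 28.9 CPM and S100a9 at 46.8 ± 52 against 46.2 ± 48.1 CPM (SD). For both, 3 of 6 detergent B libraries were above the detergent A mean in log2 CPM, so their direction is not settled. Il33, Tslp, Ccl11 and Il1b were at 0.686, 1.26, 1.32 and 0.653. Il1b was at 12 ± 10.6 against 18.3 ± 22.7 CPM (SD), with 59.9 CPM in detergent A replicate 1. In log2 CPM, 3 of 6 detergent B libraries were below the detergent A mean. No list passed, the lowest adjusted p being 0.1948 for type 2 inflammation, with a score 0.45 higher with detergent B (exact permutation test). These values leave open whether the detergents act alike.

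Across the 16836 genes the log2 fold changes of the detergents had a Pearson r of 0.853 and a covariance of 0.1292. Genes are not independent replicates, and both comparisons use the same PBS libraries. Unchanged groups simulated against those libraries gave r = 0.509 and a covariance of 0.0318, which leaves a covariance of 0.0974. With the PBS libraries split 3 and 3, over 20 ordered splits, r averaged 0.613 and the covariance 0.1037. The hair keratins score differed from PBS by -2.81 with detergent A and -2.94 with detergent B, and neither the simulation nor the split of the PBS libraries removes genes that move with it. Of the 32 genes called with detergent A, 25 were also called with detergent B in the same direction, 9 higher and 16 lower, and Degs2, Il1f8, Glrx, Twf1, Cpeb2 and Zfp772 were among those higher. Independent lists of these sizes would share 0.1775 higher and 0.2486 lower genes, a value that leaves out the shared PBS libraries. Simulated unchanged groups shared 0, but 0 of the 20 runs called a gene for detergent B, so that count says nothing of the overlap. With the PBS libraries split, 0 genes were shared in each of the 20 splits, where only 5 called any gene for detergent A and 7 for detergent B, so these splits could show little overlap, and how much of it rests on the shared PBS libraries stays open. The 25 became 0 with the GC correction and without any one of PBS replicates 1, 2 or 3, detergent A replicates 1, 3 or 5, or detergent B replicates 5 or 6. They became 2, 7 and 9 without PBS replicate 5, detergent A replicate 4 and detergent B replicate 2, and 82, 311, 429 and 725 without detergent B replicate 4, detergent A replicates 6 and 2, and PBS replicate 6.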

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

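Tests of hair growth phase, follicle tissue, depth and treatment for the hair genes, of GC content and gene length, and of spread, depth and size of change between the detergents were chosen after the data were seen, as was the look at hair scores in the splits, whereas the count of other splits was set before. A library was singled out when its gap to the nearest library of its group was too large a share of the group's range by Dixon's criterion for 6 samples. This met 30 values of 357 groups tested, where chance would give about 17.9 for normally distributed values. Single genes were taken as CPM on a linear scale, and many were named for their results. No excess of such libraries is therefore read from this.

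PBS replicate 6 stood apart in 6 values. Its scores were 4.1 for hair follicle regulators, 1.39 for melanocyte markers and 5.15 for proliferation, each lower than the other PBS libraries. Il1f6 (29.7 CPM), Il18 (76.7 CPM) and Ocln (39.2 CPM) were higher there. Other list scores were 6.44 for late cornified envelope in detergent B replicate 3, 4.45 for tight junction in detergent A replicate 1, and 6.74 for skeletal muscle in detergent A replicate 3.

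Detergent B replicate 2 was high for S100a8 (155 CPM), S100a9 (148 CPM), Lcn2 (41.2 CPM), Sprr2d (122 CPM) and Sprr2e (41 CPM). Detergent B replicate 4 was high for Il1b (32.5 CPM) and Ndufa4 (454 CPM). Detergent B replicate 3 differed for Gpr37 (7.34 CPM), Zfp772 (35.3 CPM), Krtap1-3 (0.592 CPM) and Cldn1 (392 CPM), and detergent B replicate 1 for Prr7 (1.98 CPM). PBS replicate 1 was high for Fgf5 (2.46 CPM), Krtap1-4 (5.22 CPM) and Krtap1-3 (9.38 CPM), and PBS replicate 5 for Tslp (6.25 CPM). Among detergent A libraries, replicate 2 was high for Cldn7 (0.718 CPM) and Krtap1-3 (0.972 CPM), replicate 3 for Tslp (4.93 CPM) and replicate 4 for Cryaa (1.58 CPM), and replicate 6 was low for Prr7 (0.436 CPM).

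Hair follicle genes varied widely between libraries. Within groups, the median slope on the hair keratins score of 7 bulge stem cell markers divided by that of 12 melanocyte markers was -0.025 (-0.05 to 0.006 with each library left out), which a difference in hair growth phase may give, yet Lgr5 (slope 0.302) and Lhx2 (0.203) followed the score and some of the markers are also expressed outside the follicle, so growth phase and less follicle tissue cannot be told apart. The mean score of the 12 detergent libraries minus that of the 6 PBS libraries was -2.87 (p = 0.0168, exact two-sided permutation test over 18564 assignments), so a part in the treatment also stays open. Sequencing depth is argued against, since the score kept a share of 0.975 of its range of 7.68 on the log2 scale (0.969 to 0.982 over 20 draws) when every library was thinned at random to 17312623 counts. Across libraries its group-centred values had a Pearson r of 0.2 (p = 0.41) and a Spearman rho of 0.14 (p = 0.6) with log2 total counts, both by permutation with 18 libraries, and r = 0.14 without the 2 libraries farthest from the median depth. The thinning was chosen after this correlation, which left depth open, had been seen.

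Genes lower with detergent B were GC-rich, with a median GC content of 58.1% against 50.1% over all genes tested and 47.7% for genes that were higher. After a correction for GC content, 54 of the 182 lower genes stayed past the threshold, a share of 0.297. Their median log2 fold change went from -0.51 to -0.4 with a median SE of 0.12 before and after, so the calls ended because the folds shrank, and GC-dependent recovery of reads is a candidate explanation for part of the decreases. Gene length is argued against as their cause, since 175 of the 182, a share of 0.962, stayed after a correction for length. A treatment effect on GC-rich genes was not tested.

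Fewer genes were called for detergent A than for detergent B. A lower depth is argued against, since the mean total differed by -1.09%. The median ratio of variances, detergent A over detergent B, was 1.139, and 0.97 to 1.429 with single libraries left out. The main fit takes a single spread per gene from all 3 groups. A larger spread between the detergent A libraries would therefore enter the standard errors of both comparisons, and not widen those of detergent A alone. Smaller changes with detergent A stay open. Over 100 halvings, the changes of detergent A were 0.998 ± 0.429 (SD) of those of detergent B in 200 genes chosen on the other libraries. The median of this ratio was 0.875 and the ratio of the mean changes 0.944. The halvings share libraries, so the SD is not a sampling error.

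Other splits of the 12 libraries were compared with the real one. For detergent A against PBS, 3 of 100 splits gave at least 32 genes, the real one included. For detergent B against PBS 2 of 100 gave at least 514. Both shares were under 0.05, but the 100 splits were a random sample, with no adjustment over the comparisons. The shares therefore do not exclude chance, and the detergent A total was also 0 without any one of several libraries. The highest other splits gave 1698 and 1356 genes, more than the real ones, which points to a structure of the samples other than the treatment. The first put PBS replicates 4 and 6 with detergent A replicates 3 to 6, and the second put detergent B replicates 1 and 3 with PBS replicates 1, 2, 3 and 5. The hair keratins score averaged -3.27 on the first of these sides against 0.46 on the other, and 0.38 on the second against -3.32. For detergent B against detergent A the real count was 0, so all 100 splits reached it, and the highest other split gave 1070, with hair keratins scores of -5.84 to -3.66 on one side and -3.15 to 0.54 on the other.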

How the results depend on the processing

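Counts of genes depended strongly on the test, the libraries and the hair keratins score, and for each value below the cause was not tested unless a cause is given. The GC and length corrections, the further fits with the hair score, and the limma and GC versions of the list test were added after seeing the data. Depth limits genes of low level, such as Cldn7 at 0.182 ± 0.157 CPM and Krtap1-4 at 0.0939 ± 0.153 CPM (SD, n = 6) with detergent B.

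For detergent A against PBS, the main counts were 9 higher and 23 lower. They were 470 and 327 by DESeq2, 1892 and 2022 by voomWithQualityWeights, and 0 and 0 with the replicate block, with the hair keratins score as a covariate, with that covariate and PBS replicate 6 left out, with the GC correction and in the test against 1.5-fold, which demands larger changes. Length correction gave 55 and 63. Higher genes numbered 16 with upper-quartile factors, 41 with at least 1 CPM in at least 6 libraries, 2 with only the 12 libraries compared and 3 with the hair covariate in voomWithQualityWeights. Lower genes numbered 43 with that last fit and 100 with the hair covariate in DESeq2. Leaving out single libraries gave 0 to 565 higher and 0 to 343 lower. The total was 0 without PBS replicates 1, 2 or 3, detergent A replicates 1, 3 or 5, or detergent B replicates 5 or 6. It was 2 without PBS replicate 5 (Gm17767 and Ddit4), 8 without detergent A replicate 4, 21 without PBS replicate 4, 188 without detergent B replicate 4, 769 without detergent A replicate 6, 847 without detergent A replicate 2 and 888 without PBS replicate 6.

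For detergent B against PBS, the main counts were 332 and 182. They were 829 and 562 by DESeq2 (513 of the 514 genes kept), 2563 and 2511 by voomWithQualityWeights, 182 and 69 with no filter, and 170 and 54 with the skeletal muscle score as a covariate. With the hair keratins score as a covariate they were 0 and 0, with PBS replicate 6 also left out 0 and 1 (Gm37352), in DESeq2 88 and 89, and in voomWithQualityWeights 56 and 75. The test against 1.5-fold gave 0 and 0, only the 12 libraries compared gave 505 higher, and the GC correction gave 61 lower. Leaving out single libraries gave 24 to 1157 higher and 3 to 731 lower. The total was 28, 30, 82, 150 and 262 without PBS replicates 3, 2, 5, 1 and 4, 87, 99, 153 and 176 without detergent B replicates 2, 5, 6 and 4, and 326 without detergent A replicate 5, against 891 and 1047 without detergent B replicates 1 and 3 and 1888 without PBS replicate 6.

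For detergent B against detergent A, counts were 0 and 0 in all settings, single libraries left out included (0 to 0), except 3 higher and 2 lower in DESeq2 with the hair covariate, namely Il1f6, Gm43940 and Iglc1, and Hnf4g and Rph3a. Il1f6 had a log2 fold change of 0.79 ± 0.17 (SE). Gm43940 and Iglc1 had 18.42 and 17.62, and Hnf4g and Rph3a -17.29 and -18.71 (SE 2.83 to 3.7). DESeq2 was run without the filter on low counts, and values of that size are not read as changes between the detergents.

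Lists called for detergent A were 0 in the main test, 28 with camera's preset correlation and 0 to 2 with single libraries left out. For detergent B the main 11 became 23 with camera's preset correlation, which kept 10 of them and lost tight junction (adjusted p = 0.08879), 0 with its estimated correlation, 0 with the replicate block, where 64 sign flips limit how small a p can be, 0 with the hair keratins score as a covariate in limma, and 8 to 20 with single libraries left out, with the highest count without detergent B replicate 3 and 18 without PBS replicate 6. The limma fit changed the test as well as adding the covariate. Of the 11 lists, 8 stayed called in all 12 fits that left out 1 of the libraries compared. Stress keratins, inflammasome and mitochondrial respiration did not (highest adjusted p = 0.06818, 0.07084 and 0.0974, exact permutation test). For detergent B against detergent A, 0 lists became 21 with camera's preset correlation and stayed at 0 to 0 with single libraries left out. The correlation of the fold changes went from 0.853 to 0.613 with split PBS libraries, where each comparison also had 3 PBS libraries in place of 6, and ranged from 0.806 to 0.886 with single libraries left out (jackknife SE 0.081). Genes called with both detergents went from 25 to 555 by DESeq2, 0 with the GC correction, and 0 to 725 with single libraries left out.

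Whether replicate numbers pair the samples was not tested and stays open. Deviations of same-numbered libraries correlated from -0.35 to 0.55, and 0, 1 and 3 of 6 libraries correlated best with their own number in the 3 comparisons. The replicate block gave 0 genes for detergent A (3332 at an unadjusted p under 0.05) and 252 higher and 125 lower for detergent B. Over the named genes and the alternatives, 2851 values kept their direction and side of the threshold, 701 kept the direction and lost the call, 38 gained one, 39 that passed in neither fit changed sign, and none that passed did. For lists the numbers were 2308, 61, 85 and 108.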

Other observations

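The fits with the hair keratins score and the test of that score were added after the results were seen, and the list tests were not. Lists of immune cells gave no call with either detergent by the exact permutation test. With detergent A, camera with a preset correlation called dendritic and Langerhans cell, T cell and mast cell markers (adjusted p = 6.659e-05, 0.01272 and 0.04147, against 0.4344, 0.4697 and 0.4697 with an estimated correlation). Their scores differed from PBS by -0.45, -0.28 and -0.3 (adjusted p = 0.1623, 0.1906 and 0.1732, exact permutation test), and 5 of 18 dendritic genes (Cd209a, Cd83, Ciita, Clec9a and H2-Ab1) and 1 of 22 T cell genes (Cd2) fell adjusted over the list alone. These genes are outside the naming rule and were named after their values were seen. With detergent B the scores differed from PBS by 0.14 for neutrophil markers, 0.18 for monocyte and macrophage markers, -0.07 for T cell markers, 0.04 for mast cell markers and 0.01 for eosinophil markers, of which only 4 genes were measured (adjusted p from 0.3744 to 0.961, exact permutation test). Type 2 inflammation was at 0.18 and type 17 inflammation at -0.16 (adjusted p = 0.3426 and 0.6672, exact permutation test). The median log2 fold changes of the eosinophil and type 17 lists, -0.07 and 0.05, had the opposite sign to their scores. Xenobiotic response genes had a score 0.47 higher with detergent B and missed the threshold (adjusted p = 0.05566, exact permutation test), and Gsta1 and Cyp3a13 were the 2 of 18 that rose over all genes tested, both outside the naming rule. Immediate early genes had a score of -0.57 with the same adjusted p, and 3 of 22 fell adjusted over the list alone.

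Among hair follicle regulators, Bmp4, Fgf5 and Sox9 fell with detergent B (log2 fold changes of -0.6, -1.47 and -0.44), while the list score of -0.85 did not pass (adjusted p = 0.08893, exact permutation test). Without PBS replicate 6 that score was -1.11 and passed (adjusted p = 0.03247, exact permutation test). It did not pass with any other of the compared libraries left out. Bmp4 and Sox9 fall outside the naming rule. With the hair keratins score as a covariate in limma, the differences of the cornified envelope, small proline-rich and barrier lipid scores between detergent B and PBS were 0.43, 1.55 and 0.35 in place of 0.74, 1.8 and 0.53, each with an adjusted p of 0.0906. Late cornified envelope, proteases, inflammasome and tight junction had differences of 0.66, 0.37, 0.28 and -0.21 in place of 1.12, 0.58, 0.43 and -0.18, with the same adjusted p, and antimicrobial peptides 0.64 in place of 0.77 (adjusted p = 0.0974). Stress keratins and mitochondrial respiration had 0.74 and 0.15 in place of 1.04 and 0.21 (adjusted p = 0.269 for both), and epithelial alarmins 0.21 in place of 0.48 (adjusted p = 0.3569). The score may itself be changed by the treatment, in which case this adjustment removes part of the effect, and the detergent libraries had a lower score than PBS (p = 0.0168, exact permutation test).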
